A study of Mus musculus with 3 samples.

How the data were processed

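RNA sequencing libraries were made from mouse neural stem cells with a stranded total RNA kit after removal of ribosomal RNA, per the labels' protocols. The labels gave 3 libraries, 1 of cells with a control hairpin (shControl) and 2 of cells with a hairpin against PHF2 (shPHF2). Per the submitters' processing notes, HISAT2, HTSeq, DESeq2 and the genome build mm10 were used; versions, the gene annotation and whether counting used the strand are not given in the sources used here. Genes that overlap or lie antisense to each other are therefore uncertain.

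The deposited table holds, for each gene and library, a signal that the authors obtained by dividing read counts by the library's DESeq2 size factor, per the file headers and the values. Every value was a whole multiple of the smallest value above 0 in its column (100% of values, within 0.001 of a whole number), so whole reads were recovered; the size factors were 1.00 for shControl, 1.20 for shPHF2 replicate 1 and 0.829 for replicate 2. The deposited table also gives the authors' log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value from DESeq2, per the file headers. Adjusted p-values were empty for 4280 genes and stayed so. No library column was left unused (0 columns).

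The table has 16977 genes and 4 rows that name no gene, which were kept out of library sizes and tests. In the order shControl, shPHF2 replicate 1 and replicate 2, 42.7%, 44.0% and 38.7% of reads in the table fell on no counted feature. This class can hold reads in introns, so they need not lie outside genes. In the same order, reads of low alignment quality made up 17.0%, 15.9% and 20.5%, and unaligned reads 1.18%, 1.22% and 1.78%. Ambiguous reads made up 0.461%, 0.430% and 0.434%. Reads in genes made up 38.6%, 38.5% and 38.5%. How reads that align equally well to several copies of a gene were handled is not given in the sources used here. If they were dropped, the values of histone, ribosomal protein and other repeated genes are too low.

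Values were tested as log2(value + 1) with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, for the 14148 genes with a mean of at least 10 over the 3 libraries, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on that scale and understate the change of low genes. The design has 1 residual degree of freedom, which comes from the shPHF2 libraries, moderated by 6.94 prior degrees of freedom; the lone control is assumed to vary like them. The shPHF2 libraries were counted as 2 samples because the series describes them as biological replicates. They differed by more than counting noise (chi-square over its degrees of freedom 58.9 for 14185 genes with at least 20 reads), which separate preparations of 1 sample would do too. The deposited table names replicate 2 in another form than the other libraries, and whether it came from another batch is not given in the sources used here. A batch would be part of the residual spread. For genes with 1 to 3 control reads the ratio of reads is given with an exact Poisson-based 95% interval, which covers counting error only.

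In 20 simulated data sets drawn for the 14148 genes from the real means, library sizes and dispersions, with 200 genes changed, limma recovered 40.2% of genes changed 2-fold and 78.5% of those changed 4-fold, and 11.4% of its calls were false. edgeR recovered 40.3% and 78.7%, with 9.63% false. With no gene changed, limma called a median of 2 genes and at most 9. Simulated genes vary independently of each other, which real genes need not do. The simulated control had the same dispersions as the shPHF2 libraries, and the 200 changed genes were fewer than the 2027 called in the real data. The false share may therefore differ there.

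The 29 gene lists were fixed before the data were examined: S phase; G2 and M phase; G1 cyclins, CDK inhibitors and E2F-RB; replication-dependent histones; double-strand break and crosslink repair; p53 targets; RNA-DNA hybrid processing; H3K9 methylation; neural stem and radial glia; proneural and intermediate progenitors; neurons; axon guidance and cell adhesion; astrocytes; oligodendrocyte lineage; microglia and macrophages; endothelium and pericytes; fibroblasts and extracellular matrix; erythroid cells; interferon response; immediate early genes; unfolded protein and integrated stress responses; glycolysis and hypoxia; cholesterol synthesis; Notch, BMP and TGF-beta; Wnt and Shh; ribosomal proteins; mitochondrially encoded genes; imprinted genes; and clustered protocadherins. The mitochondrially encoded list had 0 genes in the table used here and was not analysed. The other 28 were tested with camera at the preset correlation of 0.01 and at an estimated one, adjusted over the lists, and their medians were ranked among 10000 random lists matched on mean expression. With an estimated correlation camera's test has the 1 residual degree of freedom of the design, so it could hardly call any list. Lists overlap, and Ccne2, Fancd2, Cbx5 and Btg2 count in more than 1. With the 4 list members that had no control read set to a floor of 3 reads, no list median changed.

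Named genes followed a rule also fixed before the data were examined: Phf2; in each direction the 12 genes with the largest change among those called, with a mean of at least 100, both shPHF2 libraries on the same side of the control and a symbol other than Gm with digits or Rik; and in each list up to 4 called members with the largest change, plus, where fewer than 2 were called, the 2 most abundant others. Values of some genes that the rule names are not reported here. Coordinates, transcript length and GC content came from GENCODE M21 (GRCm38, the same assembly as mm10) by gene symbol, which matched 98.9% of genes. The alternatives were pseudocounts of 0.5 and 5, no filter or a minimum mean of 50, TMM scaling, quantile normalization, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, the authors' adjusted p, limma without trend, a 2-fold minimum, leaving out each shPHF2 library, and, added later, a correction for GC content and transcript length by splines with 4 degrees of freedom each. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.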

Results

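Total RNA depleted of ribosomal RNA was sequenced from cultured mouse neural stem cells, the dividing progenitors of the embryonic brain, taken here from C57BL/6J embryos. The cells had been infected with a lentivirus that carried either a control short hairpin RNA (shControl) or a hairpin against Phf2 (shPHF2). PHF2 is a PHD-finger protein of the histone demethylase family that acts on methylated lysine 9 of histone H3 (H3K9). There were 3 libraries, 1 of shControl and 2 of shPHF2, the latter described as biological replicates. The deposited table accounted for 85219384 reads in the shControl library, 96663129 in shPHF2 replicate 1 and 68231147 in shPHF2 replicate 2. Of these, 32898139, 37171026 and 26302177 reads were assigned to genes, in the same order, and 16211, 16578 and 16265 genes had at least 1 read. All values below are normalised read counts, the reads of a gene divided by the size factor of its library. The shControl values come from a single library, so their error could not be estimated.

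Phf2 itself was lower in both shPHF2 libraries. It had 2593 normalised reads in shControl, 985 in shPHF2 replicate 1 and 714 in replicate 2, a shPHF2 mean of 849 ± 192 (SD, n = 2). The mean was 32.8% of the control, with 38.0% in replicate 1 and 27.5% in replicate 2. The log2 fold change was -1.63 with a standard error of 0.24 (limma, adjusted p = 0.0085). The gene lies on chromosome 13 from 48801750 to 48871119 on the minus strand (GENCODE M21, GRCm38), and the reads counted are those over its annotated exons as a whole.

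**Figure D1:**
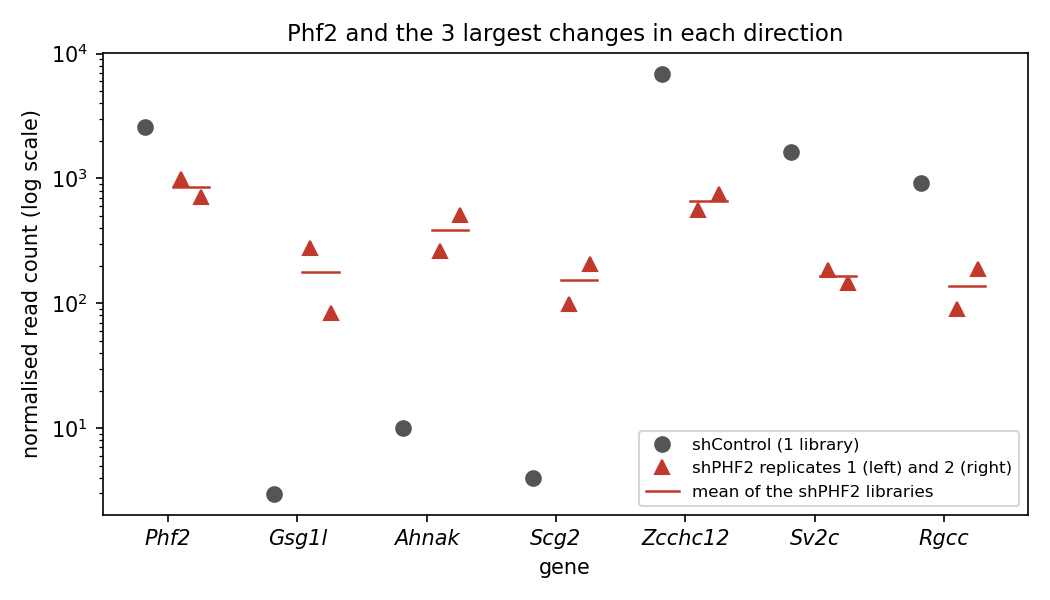
Normalised read counts (log scale) of Phf2 and, among called genes with a mean of at least 100, of the 3 with the largest rise and the 3 with the largest fall, in each of the 3 libraries; circles are the shControl library, triangles the shPHF2 libraries and the short lines their means. Phf2 lies at 2593 in shControl and at 985 and 714 in the shPHF2 libraries, and for each of the other genes both shPHF2 libraries lie on the same side of the control.

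The comparison of shPHF2 with shControl asks which transcripts differ when Phf2 is lowered in these cells. Of 14148 genes with a mean of at least 10, 2027 passed the test, 1021 of them higher and 1006 lower in shPHF2 (limma with a mean-variance trend, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were found for 704 of the higher and 515 of the lower genes. The median absolute difference over all genes tested was 0.21 on the log2 scale between the shPHF2 libraries, 0.40 between replicate 1 and the control, and 0.45 between replicate 2 and the control. The authors' deposited table called 2032 genes, 1021 higher and 1011 lower, and shared 914 of the higher and 951 of the lower genes with the limma test. The count depends on the setting: limma called 0 genes without the trend, with quantile normalization and with no filter on low values, where 3300, 3700 and 3893 genes had an unadjusted p under 0.05, while edgeR called 2147 and DESeq2 2014 genes. In simulated data of this design with 200 genes changed, 11.4% of limma's calls were false at the 0.05 threshold, so single calls near it are less certain than the threshold states. A control culture that differed by itself was not simulated, so the real false share may differ.

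Among the genes with a mean of at least 100, several of those that rose most were close to undetected in the control. Gsg1l, an auxiliary subunit of AMPA-type glutamate receptors on chromosome 7 (125878420 to 126082411), went from 3 reads in shControl to a shPHF2 mean of 179 ± 136 normalised reads (SD, n = 2). The ratio of its reads was 65.8, with a 95% counting interval of 22.3 to 320.2. Ahnak, a giant scaffold protein gene on chromosome 19 (8989284 to 9076914), rose from 9.97 to 386 ± 178 (SD, n = 2), a log2 fold change of 5.06 (SE 0.50; limma, adjusted p = 0.0040). Scg2, which encodes the secretory granule protein secretogranin II on chromosome 1 (79434669 to 79440120), rose from 3.99 to 152 ± 76.2 (SD, n = 2), a log2 fold change of 4.85 (SE 0.65; limma, adjusted p = 0.0068). The angiotensin receptor gene Agtr2 rose by 4.69 on the log2 scale, to 281 ± 9.01 (SD, n = 2) from 9.97. Ankrd34c was the most abundant gene of this group and rose from 115 to 2511 ± 467 (SD, n = 2), a log2 fold change of 4.43 (SE 0.24; limma, adjusted p = 0.0011). The interferon-inducible GTPase gene Igtp rose by 4.44, Cytip by 4.04, Trim12c by 3.88, the adhesion molecule gene Icam1 by 3.85 and Ptprn, a dense-core vesicle protein gene, by 3.84 on the log2 scale. Cd38 rose by 3.50 and the calcitonin receptor partner gene Ramp1 by 3.45. Single replicates weighed on several of these means. In the order replicate 1 and replicate 2, Gsg1l had 275 and 83.2 normalised reads, Cd38 had 134 and 411, and Ramp1 had 172 and 1049. Icam1 had a mean of 201 ± 179 (SD, n = 2) and log2 fold changes of 2.79 in replicate 1 and 4.91 in replicate 2. Without replicate 2, Scg2 stood at 98.4 and Ptprn at 128 normalised reads, and the log2 fold change of Igtp was 3.86. Ramp1 was not called by DESeq2 (adjusted p = 0.11), and neither Ramp1 nor Icam1 by limma after a correction for GC content and transcript length chosen after seeing the data (adjusted p = 0.096 and 0.065). Trim12c and Igtp belong to families of similar genes whose reads the counting could have split.

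Among genes with the same minimum mean, those that fell most were well covered in the control, which that minimum builds in. Zcchc12, a zinc-finger coactivator gene on chromosome X (36195904 to 36199158), fell from 6863 to 654 ± 141 normalised reads (SD, n = 2), a log2 fold change of -3.41 (SE 0.23; limma, adjusted p = 0.0023). Sv2c, a synaptic vesicle glycoprotein gene on chromosome 13 (95954594 to 96132577), fell from 1631 to 165 ± 27.1 (SD, n = 2), a log2 fold change of -3.31 (SE 0.29; limma, adjusted p = 0.0036). Rgcc, a regulator of cell cycle gene on chromosome 14 (79288756 to 79301645), fell from 911 to 138 ± 69.1 (SD, n = 2), a log2 fold change of -2.81 (SE 0.45; limma, adjusted p = 0.010). The laminin gene Lama1 changed by -2.64 on the log2 scale, the cationic amino acid transporter gene Slc7a2 by -2.62 and the connexin gene Gjc3 by -2.55. Pno1, needed for assembly of the small ribosomal subunit, changed by -2.52, from 2294 to 399 ± 28.2 (SD, n = 2). Mthfd2, an enzyme of mitochondrial one-carbon metabolism, changed by -2.41, from 2996 to 561 ± 12.8 (SD, n = 2). Olfml3 changed by -2.50, the cyclic GMP phosphodiesterase gene Pde9a by -2.48, the GABA transporter gene Slc6a11 by -2.37 and the peroxidase gene Lpo by -2.23. In the order replicate 1 and replicate 2, Rgcc had 89.2 and 187 normalised reads, Lama1 had 153 and 63.9, Gjc3 had 283 and 84.4, Pde9a had 475 and 235.1, and Lpo had 342 and 903. Gjc3 and Lpo were not called by DESeq2 (adjusted p = 0.26 and 0.22) or by limma after the GC and length correction (adjusted p = 0.086 and 0.060).

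Genes of DNA replication were lower almost without exception. Of 47 S phase genes tested, 44 fell and 0 rose over all genes tested, and 47 fell when adjusted over the list alone (limma). The median log2 fold change of the list was -1.21, with -1.13 in replicate 1 and -1.29 in replicate 2. Cyclin E2 (Ccne2) fell from 1746 normalised reads to 546 in replicate 1 and 563 in replicate 2, the single-strand DNA binding subunit gene Rpa2 from 3220 to 1134 ± 27.7 (SD, n = 2), and the deubiquitinase gene Usp1 from 7767 to 2860 ± 332 (SD, n = 2). Dscc1, of the clamp-loading complex for sister chromatid cohesion, fell from 357 to 114 ± 15.6 (SD, n = 2), a call lost with the GC and length correction. The list as a whole was lower than other genes (camera, preset correlation, adjusted p = 8.1e-28), and not with a correlation estimated from these libraries (adjusted p = 0.74 with an estimated correlation). The latter test has 1 residual degree of freedom and could hardly call any list, here and below.

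The replication-dependent histone genes, whose transcripts are made mainly during S phase, were lower too. Of 57 tested, 52 fell and 0 rose, and 56 fell when adjusted over the list alone (limma). Hist1h4h, Hist2h2be, Hist2h4, Hist3h2ba and Hist4h4 were the 5 that did not pass, named after their values were seen, at log2 fold changes of -1.28, -0.89, -1.40, -0.90 and -0.99. The median log2 fold change was -1.54, and it was -1.79 in replicate 1 and -1.26 in replicate 2. Hist1h2an fell from 1820 to 456 ± 189 normalised reads (SD, n = 2), Hist1h2ah from 1858 to 486 ± 188 (SD, n = 2), Hist1h2ac from 2484 to 653 ± 257 (SD, n = 2) and Hist1h2bp from 1054 to 293 ± 81.3 (SD, n = 2). Camera with the preset correlation gave an adjusted p of 1.8e-29, and the call was lost with an estimated one (adjusted p = 0.74 with an estimated correlation). Histone genes are near-identical copies, so values of single members are uncertain.

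Mitotic genes had a lower median as a list, more so in replicate 2. Of 54 G2 and M phase genes, 29 fell and 0 rose, and 46 fell when adjusted over the list alone (limma). Plk1, Aurka, Cdc20, Tpx2 and Mki67 passed over the list alone only, and are named after their values were seen. Their adjusted p over all genes was 0.053 to 0.097 (limma). The list's median log2 fold change was -0.96, with -0.68 in replicate 1 and -1.23 in replicate 2. DNA topoisomerase II alpha (Top2a) fell from 41613 to 15284 ± 4215 normalised reads (SD, n = 2), the chromatin protein gene Hmgb2 from 1852 to 597 ± 189 (SD, n = 2), the nuclear envelope gene Tmpo from 26384 to 9286 ± 1294 (SD, n = 2) and heterochromatin protein 1 alpha (Cbx5) from 70749 to 23120 ± 3582 (SD, n = 2). The list was lower by camera (adjusted p = 6.8e-18), and not with its own correlation (adjusted p = 0.74 with an estimated correlation). After the GC and length correction, 14 members passed, with a median of -0.89.

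Of 32 genes for G1 cyclins, CDK inhibitors and the E2F and RB families, 11 fell and 0 rose, and 13 fell when adjusted over the list alone (limma). Besides Ccne2, the members that fell included the ubiquitin ligase gene Skp2 (5490 to 1952 ± 301; SD, n = 2), the E2F repressor gene E2f7 (1792 to 732 ± 68.4; SD, n = 2) and the pocket protein gene Rbl1 (3739 to 1558 ± 336; SD, n = 2). Among those not called by limma, the authors' adjusted p called Ccnd2 and Cdkn1a higher, at 0.81 and 0.73 by limma, both named after their values were seen. The list's median was -0.38 on the log2 scale (camera, adjusted p = 0.0033), and the call was lost with an estimated correlation (adjusted p = 0.74 with an estimated correlation).

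Among 50 genes for repair of DNA double-strand breaks and crosslinks, 26 fell and 0 rose, and 33 fell when adjusted over the list alone (limma). Fancd2, a central protein of the Fanconi anaemia pathway, fell from 1543 to 571 ± 113 normalised reads (SD, n = 2), the checkpoint kinase gene Chek1 from 2204 to 821 ± 60.0 (SD, n = 2), Fancb from 1082 to 417 ± 83.4 (SD, n = 2) and Clspn, which encodes the replication checkpoint protein claspin, from 4147 to 1592 ± 204 (SD, n = 2). The list's median was -0.86, with -0.69 in replicate 1 and -1.02 in replicate 2 (camera, adjusted p = 1.9e-14; adjusted p = 0.74 with an estimated correlation). Of 20 genes that process RNA-DNA hybrids, 7 fell and 0 rose, and 9 fell when adjusted over the list alone (limma). They included Brca2 (4366 to 1744 ± 328; SD, n = 2), the ribonuclease H2 subunit gene Rnaseh2a (1233 to 582 ± 10.1; SD, n = 2), the splicing factor gene Srsf1 (45139 to 21447 ± 569; SD, n = 2) and again Fancd2. The median was -0.45 (camera, adjusted p = 1.4e-04; adjusted p = 0.74 with an estimated correlation).

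Genes of the H3K9 methylation machinery other than Phf2 moved in both directions. Of 26 tested, 7 fell and 3 rose, and 8 fell and 3 rose when adjusted over the list alone (limma). The H3K9 methyltransferase gene Suv39h2 fell from 1858 to 713 ± 33.5 normalised reads (SD, n = 2), the maintenance DNA methyltransferase gene Dnmt1 from 15492 to 6701 ± 1081 (SD, n = 2), Cbx3 from 601 to 270 ± 14.8 (SD, n = 2), and Cbx5 as given above. The Cbx3 call was lost with the GC and length correction. The 3 genes that rose, named after their values were seen, were the demethylase genes Jhdm1d and Kdm4a and the PHF2 partner gene Arid5b, by 0.85, 0.65 and 0.86 on the log2 scale. The list's median was -0.25 (camera, adjusted p = 0.035; adjusted p = 0.75 with an estimated correlation), and its call was also lost with a minimum mean of 50 (adjusted p = 0.053) and with quantile normalization (adjusted p = 0.17). That median lay at percentile 4.26 among random lists matched on mean expression, which does not count as a call by rank.

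Targets of the tumour suppressor p53 were higher as a list. Of 35 tested, 6 rose and 2 fell, and 8 rose and 2 fell when adjusted over the list alone (limma). The membrane protein gene Perp rose from 114 to 562 ± 317 normalised reads (SD, n = 2), with 338 in replicate 1, Ano3 from 1449 to 4132 ± 713 (SD, n = 2), the pro-apoptotic gene Bbc3 from 269 to 679 ± 147 (SD, n = 2) and the anti-proliferative gene Btg2 from 1045 to 2509 ± 494 (SD, n = 2). The 2 that fell, named after their values were seen, were Zmat3 and 9630033F20Rik, with log2 fold changes of -0.99 and -0.75. The median was 0.53, with 0.22 in replicate 1 and 0.68 in replicate 2 (camera, adjusted p = 0.0030; adjusted p = 0.74 with an estimated correlation). With the GC and length correction, 3 members rose and 2 fell, and Perp was not called.

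Interferon response genes had a higher median as a list, with a larger shift in replicate 2. Of 30 tested, 9 rose and 2 fell, and 13 rose and 2 fell when adjusted over the list alone (limma). Parp14 rose from 30.9 to 241 ± 16.1 normalised reads (SD, n = 2) and Ifi35 from 28.9 to 231 ± 14.3 (SD, n = 2). The ubiquitin ligase gene Trim25 had 1 read in shControl and 22.5 and 221 normalised reads in the shPHF2 libraries, a read ratio of 104 with a 95% counting interval of 18.4 to 4121. For Ifi44, with 2 reads in shControl, the read ratio was 28.9 with an interval of 7.83 to 241.7, and replicate 1 had 40.0 normalised reads. Trim25 was not called with a pseudocount of 5 (limma, adjusted p = 0.063) or with the GC and length correction (adjusted p = 0.082). Ifit2 and Gbp3 fell, with log2 fold changes of -1.92 and -1.45, and are named after their values were seen. The list's median was 0.92, with 0.62 in replicate 1 and 1.36 in replicate 2 (camera, adjusted p = 7.8e-04; adjusted p = 0.74 with an estimated correlation).

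Stress lists were not called. Of 28 immediate early genes, 4 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone (limma). Ier3 rose from 454 to 1814 ± 551 normalised reads (SD, n = 2), Arc from 894 to 1957 in replicate 1 and 4015 in replicate 2 and Klf6 from 5984 to 10352 ± 127 (SD, n = 2), besides Btg2. Ier5 fell by 0.74 on the log2 scale and Klf2 passed over the list alone at 1.73, both named after their values were seen. The median was 0.12 (camera, adjusted p = 0.43), and its sign differed between the replicates, with -0.17 in replicate 1 and 0.35 in replicate 2. Of 29 genes of the unfolded protein and integrated stress responses, 2 rose and 2 fell, over all genes and adjusted over the list alone (limma). The cystine transporter gene Slc7a11 rose from 881 to 4930.5 in replicate 1 and 2230.5 in replicate 2 and Ddit4 from 1132 to 2760 ± 329 (SD, n = 2), while Mthfd2 and the serine hydroxymethyltransferase gene Shmt2 (4861 to 2002 ± 126; SD, n = 2) fell. Slc7a11 was not called by DESeq2 (adjusted p = 0.14), nor Arc by limma with the GC and length correction. The list's median was -0.13 (camera, adjusted p = 0.43).

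Neural stem cell identity genes did not move as a list. Of 29 neural stem and radial glia genes, 2 rose and 1 fell, and 1 rose and 1 fell when adjusted over the list alone (limma). Sox2 rose from 5893 to 9466 ± 915 normalised reads (SD, n = 2) and Sox3 fell from 2718 to 1169 ± 138 (SD, n = 2). The Sox2 call was lost with edgeR (adjusted p = 0.054) and with the GC and length correction. With the GC and length correction, 0 members rose, while 4 had an unadjusted p under 0.05 with limma before it, edgeR called 1 higher and DESeq2 4. The list's median was -0.03 (camera, adjusted p = 0.90), with the opposite sign in each library, at 0.0071 in replicate 1 and 0.075 in replicate 2. Of 14 proneural and intermediate progenitor genes, Btg2 rose while Sox11 (21957 to 8951 ± 898; SD, n = 2) and the Notch ligand gene Dll1 (1660 to 847 ± 149; SD, n = 2) fell, with 2 higher and 3 lower when adjusted over the list alone (limma). Those added over the list alone, named after their values were seen, were Neurod1 at 2.83 and Insm1 at -0.93. The median was -0.21, with -0.03 in replicate 1 and -0.73 in replicate 2 (camera, adjusted p = 0.56).

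Neuron genes were higher as a list. Of 28 tested, 4 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone (limma). Besides Scg2, the GABA-synthesizing enzyme gene Gad1 rose from 138 to 610 ± 156 normalised reads (SD, n = 2), the synaptic vesicle gene Syp from 266 to 687 ± 106 (SD, n = 2) and the stathmin family gene Stmn3 from 529 to 1031 ± 58.2 (SD, n = 2). Elavl4 fell by 0.86 on the log2 scale and Scg3 passed over the list alone at 0.72, both named after their values were seen, and Elavl4 was not called with the GC and length correction. The median was 0.56, with 0.33 in replicate 1 and 0.80 in replicate 2 (camera, adjusted p = 0.015; adjusted p = 0.74 with an estimated correlation), and the call was lost with quantile normalization (adjusted p = 0.051). Of 38 axon guidance and cell adhesion genes, 8 rose and 0 fell, and 9 rose when adjusted over the list alone (limma). The ephrin gene Efnb2 rose from 603 to 3259 ± 185 (SD, n = 2), the netrin receptor gene Unc5c from 451 to 1659 ± 41.2 (SD, n = 2), Ephb1 from 470 to 1414 ± 56.0 (SD, n = 2) and the semaphorin receptor gene Nrp1 from 2014 to 4983 ± 530.5 (SD, n = 2). The median was 0.42 (camera, adjusted p = 1.4e-04; adjusted p = 0.74 with an estimated correlation).

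The clustered protocadherins, neural adhesion genes of which some share exons within a cluster, had a higher median as a list. Of 31 tested, 4 rose and 0 fell, and 5 rose when adjusted over the list alone (limma). Pcdhga2 rose from 155 to 485 ± 172 normalised reads (SD, n = 2), Pcdhb22 from 544 to 1194 ± 62.6 (SD, n = 2), Pcdhga7 from 411 to 903 ± 289 (SD, n = 2) and Pcdhb17 from 446 to 809 ± 32.5 (SD, n = 2). Pcdhgb2, named after its value was seen, passed over the list alone at 0.80. Only Pcdhb22 of these was called with the GC and length correction, and 6 members were with TMM scaling. The median was 0.67 (camera, adjusted p = 2.8e-05; adjusted p = 0.74 with an estimated correlation). Reads in shared exons cannot be assigned to single members, which concerns Pcdhga2 and Pcdhga7. The transcripts of Pcdhb22 and Pcdhb17 are as long as their genes and hold no such exon. The Pcdhga7 call was lost under a pseudocount of 5 (limma, adjusted p = 0.0504) and the Pcdhb17 call with DESeq2 (adjusted p = 0.052).

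Developmental signalling genes changed in both directions. Of 35 Notch, BMP and TGF-beta pathway genes, 5 rose and 4 fell, and 7 rose and 4 fell when adjusted over the list alone (limma). The latent TGF-beta binding protein gene Ltbp1 rose from 747 to 2807 ± 90.8 normalised reads (SD, n = 2) and the BMP target gene Id2 from 955 to 3561 ± 645 (SD, n = 2). The TGF-beta receptor gene Tgfbr1 fell from 5503 to 1500 ± 194 (SD, n = 2) and the BMP receptor gene Bmpr1b from 1756 to 624 ± 97.7 (SD, n = 2). The others called, named after their values were seen, were Notch3, Jag1 and Id1, at 1.06, 1.15 and 1.26, and Dll1 and Skil, at -0.98 and -0.95. The median was 0.16 (camera, adjusted p = 0.35). Of 36 Wnt and Shh pathway genes, 4 rose and 5 fell, over all genes and adjusted over the list alone (limma). The Wnt target gene Sp5 rose from 4.98 to 94.1 ± 30.6 (SD, n = 2), the Wnt receptor gene Fzd1 from 4106 to 13886 ± 3720 (SD, n = 2) and Shh from 271 to 733 ± 301 (SD, n = 2), while Wnt5a fell from 8612 to 3203 ± 312 (SD, n = 2). Fzd9 at 1.29, and Wnt7a, Wnt7b, Gli2 and Cdon at -1.23, -0.85, -1.07 and -0.96, were the others called, named after their values were seen. Shh was not called with the GC and length correction. The median was -0.05 and the mean 0.18, with opposite signs (camera, adjusted p = 0.94), and the median was 0.13 in replicate 1 and -0.12 in replicate 2.

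Ribosomal protein genes had a lower median as a list, with few single calls. Of 55 tested, 7 fell and 1 rose, over all genes and adjusted over the list alone (limma). Rpl15 fell from 4123 to 1237 ± 180 normalised reads (SD, n = 2), Rpl12 from 1066 to 547 ± 37.3 (SD, n = 2) and Rpl5 from 658 to 342 ± 7.36 (SD, n = 2), while Rps16 rose from 252 to 589 ± 22.4 (SD, n = 2). Rpl5 was not called by DESeq2 (adjusted p = 0.062) or with the GC and length correction, with which 3 members fell. The median was -0.45 (camera, adjusted p = 3.4e-07; adjusted p = 0.74 with an estimated correlation). These genes have many processed pseudogenes that share their reads, so single values are uncertain.

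Metabolic and imprinted lists were not called by camera, except cholesterol synthesis under the GC and length correction. Of 28 glycolysis and hypoxia genes, Bnip3 (149 to 433 ± 87.2; SD, n = 2), Pdk1 (315 to 662 ± 121; SD, n = 2) and Hk1 (1964 to 3952 ± 451; SD, n = 2) rose and Hk2 (2485 to 1234 ± 16.3; SD, n = 2) fell, with 3 higher and 1 lower also when adjusted over the list alone (limma). The median was -0.0021 and the mean 0.13, with opposite signs (camera, adjusted p = 0.48), and the median was -0.07 in replicate 1 and 0.11 in replicate 2. None of 25 cholesterol synthesis genes passed, with 0 calls also when adjusted over the list alone and with a median of -0.19 (limma; camera, adjusted p = 0.10). At an unadjusted p under 0.05 limma had 2 lower, and edgeR and DESeq2 called 0. With the GC and length correction the list was called lower, at a median of -0.24 (camera, adjusted p = 0.032; without the correction, adjusted p = 0.74 with an estimated correlation). Hmgcs1 had 19784 normalised reads in shControl and 14229 ± 181 in shPHF2 (SD, n = 2), and Cyp51 had 12445 and 9342 ± 371 (SD, n = 2). Of 21 imprinted genes, Igf2 (68.8 to 271 ± 51.7; SD, n = 2) and Igf2r (4983 to 13209 ± 3493; SD, n = 2) rose while Plagl1 (315 to 96.4 ± 13.7; SD, n = 2) and Mest (75292 to 30085 ± 6940; SD, n = 2) fell, the same numbers as when adjusted over the list alone (limma). The Pdk1 and Mest calls were lost with the GC and length correction. The median was 0.36, with 0.19 in replicate 1 and 0.36 in replicate 2 (camera, adjusted p = 0.48). It lay at percentile 98.6 among random lists matched on mean expression, which counts as a call by rank.

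Markers of other cell types gave few calls. Of 21 astrocyte genes, 3 rose and 0 fell, and 4 rose when adjusted over the list alone (limma). They were the clusterin gene Clu (96.7 to 442 ± 101; SD, n = 2), Sparcl1 (12044 to 43139 ± 12928; SD, n = 2) and S100b (331 to 972 ± 172; SD, n = 2), joined over the list alone by Id3 at 0.63, and the list's median was 0.29, with 0.10 in replicate 1 and 0.33 in replicate 2 (camera, adjusted p = 0.070). None of 14 oligodendrocyte lineage genes passed in either count: Olig1 had 37506 normalised reads in shControl and 45602 ± 10444 in shPHF2 (SD, n = 2), and Olig2 had 29320 and 26666 ± 3429 (SD, n = 2), with a list median of -0.14, -0.08 in replicate 1 and 0.07 in replicate 2 (camera, adjusted p = 0.99). At an unadjusted p under 0.05 limma had 3 of them higher and 1 lower. edgeR called Opcml higher and the authors' adjusted p called Nkx2-2 higher, at 1.40 and 2.32 by limma, both named after their values were seen. Of 9 endothelial and pericyte genes, Emcn rose from 127 to 420 ± 106 (SD, n = 2), and 2 rose when adjusted over the list alone (limma), the other being Rgs5 at 2.98. Kdr had 200.4 reads in shControl and 117 ± 55.7 in shPHF2 (SD, n = 2), Tek 78.7 and 130.2 ± 49.4 (SD, n = 2), and the median was 0.27, with 0.75 in replicate 1 and 0.27 in replicate 2 (camera, adjusted p = 0.48). Of 17 fibroblast and extracellular matrix genes, Foxc1 (1994 to 5217 ± 422; SD, n = 2) and Vcan (8432 to 15266 ± 592; SD, n = 2) rose, with 2 higher and 1 lower, Fbln1 at -0.95, when adjusted over the list alone (limma). Id3, Rgs5 and Fbln1 are named after their values were seen. That list's median was -0.0061 and its mean 0.19, with opposite signs (camera, adjusted p = 0.48), and the median was 0.49 in replicate 1 and -0.25 in replicate 2. None of 4 microglia and macrophage genes passed over all genes and 2 were higher when adjusted over the list alone (limma), with P2ry12 at 99.7 and 209 ± 6.47 (SD, n = 2) and a median of 0.71, with 0.84 in replicate 1 and 0.46 in replicate 2 (camera, adjusted p = 0.43). Alas2, the 1 erythroid gene tested, had 107 reads in shControl and 56.1 ± 19.7 in shPHF2 (SD, n = 2), and did not pass alone or over all genes (camera, adjusted p = 0.48).

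**Figure D2:**
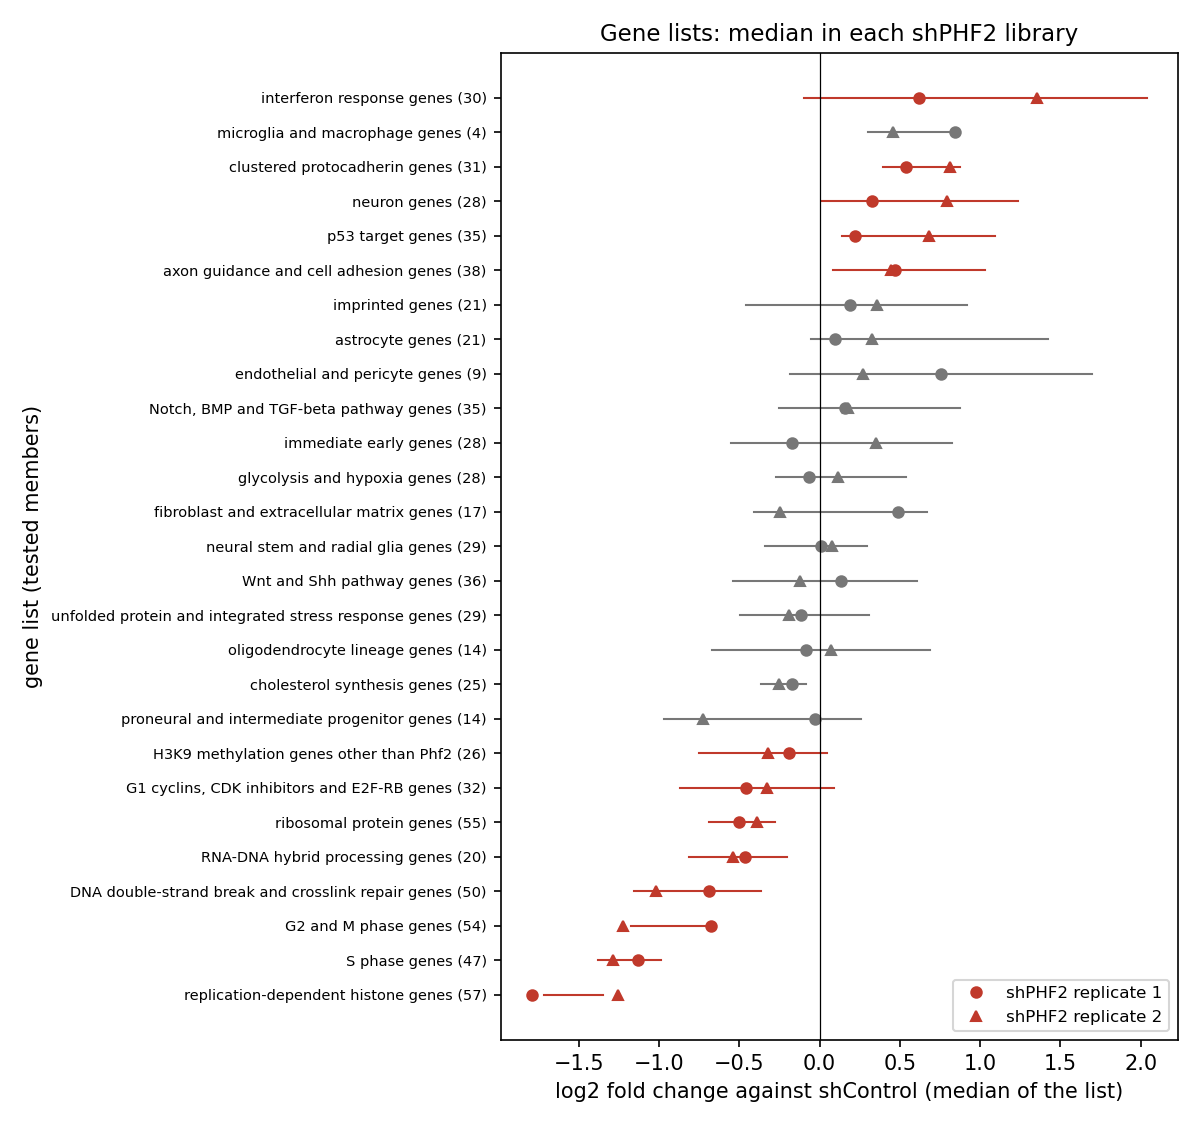
Median log2 fold change of each gene list with at least 4 tested members in shPHF2 replicate 1 (circles) and replicate 2 (triangles) against shControl; lines span the quartiles of the members' fold changes over both replicates, and red marks lists called by camera with the preset correlation. The S phase list lies at -1.13 and -1.29, the histone list at -1.79 and -1.26, and the interferon response list at 0.62 and 1.36.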

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

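The test of a stronger knockdown below was chosen after the result was seen; the tests of the length trend were set before theirs were. In shPHF2 replicate 2, 1.78% of reads were unaligned against 1.18% in shControl, and 20.5% of reads had low alignment quality against 17.0% in shControl. Both stand out because they are reads outside the gene counts whose share in a shPHF2 library was at least 1.2 times that of the control.

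The shPHF2 libraries also differed from each other in cell cycle genes. Against replicate 1, replicate 2 had higher replication-dependent histone genes (median log2 difference 0.60) and lower G2 and M phase genes (median -0.47), and genes with long transcripts were lower in it (median -0.19 in the longest of 10 equal groups of genes, 0.14 in the shortest). After removal of the trend with GC content and length, the histone difference was 0.47 (quartiles 0.27 to 0.73) and the G2 and M difference -0.50 (quartiles -0.63 to -0.37), which argues against the trend as the whole cause of either. A stronger effect of the lower Phf2 level in replicate 2 on every list would push the histone genes further down, but they were higher by 0.60 (quartiles 0.36 to 0.83), which is the pattern itself. Among called lists, the histone, G1, ribosomal protein and axon guidance medians lay nearer the control in replicate 2. The others lay further, such as S phase (-1.13 in replicate 1 and -1.29 in replicate 2), repair (-0.69 and -1.02) and interferon response (0.62 and 1.36). A stronger effect on some lists is therefore not excluded. A difference in library preparation (the deposited table names replicate 2 in another form than the other libraries) or reads lost between histone copies may account for the difference between the replicates and was not tested, and no other biological explanation was tested.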

How the results depend on the processing

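The GC and length correction, quantile normalization of the lists, limma without trend for single genes and the count of genes at least 2-fold apart were chosen after seeing the data. The count of 2027 genes lay between 1359 (GC and length correction, 1314 of them among the 2027) and 2316 (TMM scaling) under the pseudocounts, the higher minimum mean, TMM, edgeR, DESeq2, the authors' adjusted p and the correction, with 46.8% to 50.6% of calls higher. It was 0 with limma with no filter on low values, with quantile normalization and without the trend (3893, 3700 and 3300 genes at unadjusted p under 0.05; edgeR 2147, DESeq2 2014), and the cause was not tested. Without the trend the smallest adjusted p was 0.15, and the prior degrees of freedom fell from 6.94 to 2.24. With a 2-fold minimum it was 1219 by construction, 704 higher and 515 lower. No scaling moved the median of all genes by over 0.1 on the log2 scale.

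Phf2 kept its direction in each setting run for it, with -1.78 to -1.61 in the tests that called it (adjusted p 4.9e-06 to 0.027), but was not called by limma without the trend (-1.63, adjusted p = 0.16; the cause was not tested). Without shPHF2 replicate 1 or 2 its log2 fold change was -1.86 or -1.40. Leaving out either library leaves 1 against 1, so no test has residual degrees of freedom; 2827 and 2146 genes were then at least 2-fold apart, against 2345 with both.

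Of 28 lists, 13 were called with the preset correlation, and 11 to 14 under TMM, quantile normalization, a pseudocount of 5, a minimum mean of 50, the correction and the rank among random lists. The lists called were not the same throughout. By rank the imprinted list was called and the H3K9 methylation list was not. Without shPHF2 replicate 1 or 2 the medians of 8 and 5 lists moved by more than the spread between replicates. That spread is the SD of the same 2 library medians, so the comparison says little about how stable the lists are. With an estimated correlation 0 were called: the medians of the histone (-1.54), S phase (-1.21), G2 and M (-0.96) and repair lists (-0.86) were as before with adjusted p = 0.74. That test has the 1 residual degree of freedom of the design, could hardly call any list and does not tell whether the lists hold. Calls were also lost where the estimate lay below the preset 0.01, as for the axon guidance (-0.024), RNA-DNA hybrid (-0.042) and protocadherin lists (-0.024). A correlation above the preset one does not account for those losses. For the lists that fell most the estimate lay above it. It was 0.93 for G2 and M, 0.86 for histones, 0.40 for repair and 0.18 for S phase. Such estimates rest on 1 residual degree of freedom and are rough. If they held, the camera p-values of these lists at the preset correlation would be too small. Of the 114 other named genes, 105 were called. Calls lost were 105 without the trend, 18 with the correction, 6 with DESeq2, 2 with a pseudocount of 5 and 1 with edgeR, and no gene changed direction in these settings. None did so without either shPHF2 replicate. For the 12 genes named in each direction this was fixed, since the rule required both shPHF2 libraries on the same side of the control.

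No paired analysis was possible because shControl has 1 library and carries no replicate number. The depth of 26302177 to 37171026 reads in genes limits the genes near undetected in the control most, such as Gsg1l, Trim25 and Ifi44.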

Other observations

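The ribosome biogenesis and histone variant lists, and the tests of cell replacement, of other splits of the libraries, of histone variants and of the trend for histone genes, were chosen after the results were seen. Genes that build ribosomes in the nucleolus were lower. Of 102 listed, 54 fell and 0 rose over all genes (limma), with a median log2 fold change of -0.72, -0.76 in replicate 1 and -0.70 in replicate 2. The values of 34 of them had been seen before the list was written; the other 68 had a median of -0.64 with 30 falls and 0 rises. With camera the p of all 102 genes, those seen before included, was 1.2e-23, and adjusted p = 0.12 with an estimated correlation. Of 94 snoRNA genes, 80 lay below the control in both shPHF2 libraries, against 5451 of 13203 protein-coding genes, but both libraries are set against the same control. Their median was -0.76, and only Snora65 passed the test (limma, log2 fold change -1.50, named after its value was seen). Among 9 replication-independent histone variant genes, H2afy2 and H2afz fell and the median was -0.27, with -0.11 in replicate 1 and -0.41 in replicate 2 (camera, adjusted p = 0.043; adjusted p = 0.28 with an estimated correlation).

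Of the Y-linked genes, Ddx3y had 3112, 2909 and 1558 normalised reads in shControl, shPHF2 replicate 1 and replicate 2, Kdm5d 1494, 1426 and 844, and Uty 1231, 1292 and 857, while Eif2s3y had 666, 696 and 867. Xist had 10726, 9435 and 12850.

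S phase and histone genes fell together. Removal of the trend with GC content and length left the S phase median at -1.19 (quartiles -1.36 to -0.99; -1.21 before) and the histone median at -1.40 (quartiles -1.54 to -1.16; -1.54 before), so that trend does not account for it. Replacement of the stem cells by cells without their transcripts would lower stem cell genes alike, but their median was -0.0287 (quartiles -0.34 to 0.29). Cells that keep those transcripts are not covered by this. The neuron and axon guidance lists were higher (medians 0.56 and 0.42), and the astrocyte list was not called (0.29). A shift toward cells of that kind was not tested. A loss of all histone transcripts would lower the variants as much, but they stood at -0.27 (quartiles -0.46 to -0.04) against -1.54, and at -0.41 in the library where they were lower; they were still lower by camera, so a small part of that kind is not excluded. A candidate explanation, found on these data, is a smaller share of cells in S phase in the shPHF2 cultures, which would need a measure of DNA content or synthesis and was not tested; a control culture that grew faster by itself stays open too, since there was 1 control library.

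For the ribosome biogenesis genes, removal of the same trend left the median at -0.74 (quartiles -0.96 to -0.43), which argues against GC content and length as the cause. Whether their fall may follow slower growth or an effect on these genes in particular stays open and was not tested.

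The 3 libraries can be split into 1 and 2 in 3 ways, too few for a share under 0.05. Only the real split, 1 of the 3, reached 2027 genes by limma, and the highest of the other splits gave 0, where 77 and 367 genes had an unadjusted p under 0.05. Each other split pairs the control with a shPHF2 library, so their difference becomes the residual spread and few calls are built in. The counts therefore do not tell an effect of the hairpin from a control library that is odd by itself.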
